A study of Arabidopsis thaliana with 10 samples.

How the data were processed

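RNA of whole seedlings of Arabidopsis thaliana was measured on 10 Affymetrix ATH1 arrays, 1 array per sample. The seedlings had the Col-0 background and transposon insertions in both GLK genes, per the labels, and they grew in liquid culture with hygromycin under cycles of 16 h light and 8 h dark. Control samples received the solvent DMSO and the other samples received dexamethasone, a synthetic steroid used to switch on inducible transgenes. The labels used here do not name a transgene. The series title names the targets of AtGLK1, a transcription factor, as the subject. The samples form 5 groups of 2 arrays: control at 0 h, 4 h and 24 h, and dexamethasone at 4 h and 24 h. Nothing in the labels says that the 2 replicates of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

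The deposited values are signal intensities per probe set on a linear scale, made by the authors with MAS5 in GCOS, per the submitters' processing notes; the versions are not given in the sources used here. The table holds 22810 probe sets. Its trimmed mean lay between 99.9486 and 99.9532 on every array, so each array had been scaled to a common mean before deposit, and this scaling was kept. A global scaling of this kind hides any change in the total amount of messenger RNA. The table has no detection calls, so a low signal cannot be told from background, and the number of arrays limits the precision.

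Gene names came from the platform annotation supplied with the table, updated through the RefSeq gene table of assembly TAIR10.1, which was used for names only. Of the probe sets, 13513 had 1 gene in this annotation, 503 had several and 8730 had none, apart from 64 control probe sets. Of the single-gene probe sets, 13436 were renamed through RefSeq and 77 kept the platform name. Probe sets that the annotation does not list are given by their ID. GLK1 and GLK2 had 0 annotated probe sets, so no probe set was assigned to them. A probe set without a name here can still measure either of them or the induced transgene.

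The signals were transformed to log2(signal + 4.35), where the added constant is percentile 20 of all values, so log2 changes of weak probe sets are understated. Probe sets above percentile 40 of their array on at least 2 arrays were kept, which left 14575. Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) with 1 mean per group over all 10 arrays, which leaves 5 residual degrees of freedom. The average effect of dexamethasone was fitted to the 8 arrays at 4 h and 24 h with time as a covariate. P-values were adjusted by the Benjamini-Hochberg method over the probe sets kept, with a threshold of 0.05. All tests were two-sided. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

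Before the data were examined, 21 gene lists with 276 loci were fixed. A locus was measured by a probe set of that single gene, and this held for 36 loci. Lists with at least 3 tested members were tested with limma's camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. This gave 15 tests of 5 lists over the comparisons of dexamethasone at 4 h, at 24 h and on average, adjusted together. A further 16 lists were written after the annotation had been seen, because few members of the first lists were named, and their 48 tests were adjusted together as a separate family. Tests of the lists in the difference between times and in the control time courses were also added later and were adjusted within each kind of comparison and family.

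A rule for the genes named in the text was fixed before the data were examined. It took GLK1 and GLK2, and at each time of dexamethasone the 10 largest increases and decreases that passed, with both dexamethasone arrays on one side of both controls. Where fewer than 5 genes passed at a time, it took the 10 with the smallest p, given as values that did not pass. It also took up to 3 members of each list, and the 5 largest increases and decreases that passed in the other comparisons. Probe sets without a name, and the genes high on 2 arrays, were chosen after their values were seen. So were the genes named because they passed without both of those arrays. Some list members, such as PORB at 4 h and those named in the control time course, are also outside the rule. Not every list member that the rule took is named.

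The test was checked on simulated data with 50 probe sets changed at each size among 14575. In the simulated 4 h comparison 66% of changes of 1 log2 unit and 94% of changes of 2 log2 units were recovered, with 8 false calls. At 24 h the shares were 74% and 96% with 7 false calls, and for the average 82% and 98% with 5. In the simulated control comparison they were 64% and 96% with 8. A change of 0.5 log2 units was recovered in 20%, 18%, 32% and 14% of cases in these comparisons. The simulation changed many probe sets at once, by up to 4 log2 units, and drew independent noise for each. Many calls ease the adjusted threshold, so these shares overstate what is recovered where few probe sets change. In the real data 266273_at did not pass at 4 h with a log2 change of 2.59. An absence of calls therefore does not exclude changes of 1 or 2 log2 units. The alternatives tried were other added constants, filters, normalizations and thresholds, the replicate number as a block, limma without the trend, other samples in the fit or as controls, the removal of probe sets that can cross-hybridise, an estimated correlation for the lists, and the omission of each array in turn. The omission of both arrays that stand apart on the second axis of variation was added after the data were seen.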

Results

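Transcript levels were measured in seedlings that carried, per the labels, transposon insertions in GLK1 and GLK2, 2 related transcription factors that promote chloroplast development, after dexamethasone or the solvent DMSO. There were 2 arrays in each of 5 groups. The median signal per array ranged from 33.9 to 35.9. Replicate arrays correlated across probe sets with r between 0.970 and 0.987, and no pair held identical values. The largest axis of variation, 31.3% of the variance, separated the arrays at 4 h from those at 0 h and 24 h. The next axis, 23.4%, separated replicate 1 of the 24 h control and replicate 2 of dexamethasone at 4 h from the other 8 arrays.

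The first comparison asked which transcripts changed within 4 h of dexamethasone. The probe set 249035_at rose from a mean signal of 8.28 ± 1.34 to 364 ± 104 (SD, n = 2 each). Its log2 change was 4.84 (SE 0.27, limma adjusted p = 1.9e-05). Its control signals lay below percentile 40 of their arrays, where a signal cannot be told from background, so the size of the rise is uncertain. It was the 1 probe set of 14575 that passed. It has no gene in the annotation used here, so whether it measures the induced transgene, a GLK gene or a downstream gene is not known, and its rise is not counted as a downstream response. In all, 1022 probe sets had an unadjusted p below 0.05, where 729 are expected by chance. Leaving out 1 array at a time moved this count between 514 and 2038, below and above the 729, and the 514 came without replicate 2 of dexamethasone at 4 h, so no excess is shown. No single-gene probe set passed in limma. Without replicate 1 of dexamethasone at 4 h, which leaves only an array that stood apart on the second axis in that group, 80 probe sets passed, 54 higher and 26 lower. Without replicate 2 there were 2.

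Among named genes at 4 h, the smallest p belonged to UGT88A1 (AT3G16520), a UDP-dependent glycosyltransferase, with a mean signal of 280 ± 3.11 in the controls and 483 ± 13.9 with dexamethasone (SD, n = 2). Its log2 change of 0.78 (SE 0.12, adjusted p = 0.171) did not pass. LHCB4.2 (AT3G08940), a minor antenna protein of photosystem II, had 862 ± 36.0 in the controls and 1453 ± 255 with dexamethasone, a log2 change of 0.74 (SE 0.15, adjusted p = 0.396). The other 8 genes with the smallest p also did not pass. Positive values were those of AT5G48490 at 1.101, AT3G23080 at 0.81, AT1G65070 at 0.76, AT1G28580 at 0.73, AT5G02160 at 0.71 and AT2G37480 at 0.62. AT3G21465 had -1.62 and AT1G52050 had -0.66. The mean signal of AT3G21465 with dexamethasone lay below percentile 40 of its arrays, so the size of its change is uncertain.

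**Figure D1:**
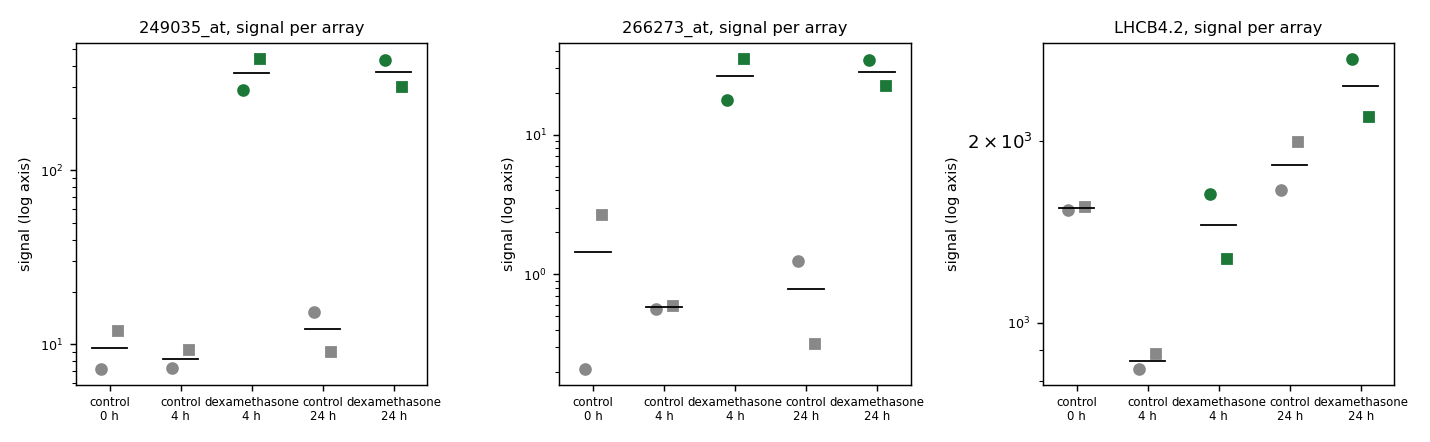
Signal of 249035_at, 266273_at and LHCB4.2 on each of the 10 arrays, on log axes, by group. Circles are replicate 1, squares replicate 2 and bars the group means; green marks dexamethasone. The 4 dexamethasone arrays lie between 290 and 438 for 249035_at, and the 6 control arrays between 7.20 and 15.3.

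The light harvesting list was higher with dexamethasone than in the controls at 4 h. Its 3 tested members of 21 were LHCB4.1, LHCB4.2 and LHCB4.3, antenna proteins of photosystem II. All 3 lay above 0, with a median log2 change of 0.37, and the list passed with camera (adjusted p = 0.0021; adjusted p = 0.164 with an estimated correlation). No member passed over all genes, and 1, LHCB4.2, passed adjusted over the list alone. The mean signal of LHCB4.2 was 1547 in the controls at 0 h, 862 in those at 4 h and 1453 with dexamethasone at 4 h. With dexamethasone at 4 h its level was thus not above that at 0 h. The samples at 0 h come from another time of day, so they are not a matched baseline. The fall in the controls and the difference at 4 h both use the 4 h control arrays, so they are not independent. At 24 h the mean signal was 1825 in the controls and 2462 with dexamethasone. Of 9 chlorophyll synthesis genes 8 lay above 0, with a median of 0.11 and adjusted p = 0.0586. HEME1, an enzyme of the tetrapyrrole pathway, had 0.28 and PORB, a protochlorophyllide reductase, -0.17. The photosystem core list (4 genes, median -0.03, adjusted p = 0.819), the electron transport list (3 genes, 0.10, adjusted p = 0.622) and the carbon fixation list (3 genes, 0.15, adjusted p = 0.300) did not pass.

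At 24 h the question was which transcripts differed after a full day of dexamethasone. The probe set 249035_at rose again, from 12.2 ± 4.39 to 368 ± 92.9 (SD, n = 2), with a log2 change of 4.50 (SE 0.27, limma adjusted p = 4.2e-05). It was the 1 probe set that passed, and 451 had an unadjusted p below 0.05, or between 307 and 1058 when 1 array at a time was left out. Without replicate 2 of the 24 h control, which leaves only an array that stood apart on the second axis as control, 8 probe sets passed, 1 higher and 7 lower. With all arrays, the 451 were fewer than the 729 expected by chance. No single-gene probe set passed in limma, and the 10 with the smallest p had adjusted p = 0.999. They included UGT88A1 at a log2 change of 0.49, rbcL (ArthCp030), the plastid gene of the large Rubisco subunit, at 0.51, AT3G05640 at 1.38 and AT5G39520 at -1.28. The other 6 were AT5G59480 at 0.58, AT3G56230 at 0.88, AT2G19385 at 0.64, AT1G80280 at 0.49, AT1G52000 at 0.89 and AT2G35260 at 0.40. The mean control signals of AT3G05640, AT3G56230 and AT1G52000 lay below percentile 40, so the sizes of their changes are uncertain.

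The light harvesting and photosystem core lists rose at 24 h. The 3 light harvesting genes had a median log2 change of 0.27 (adjusted p = 0.0110; adjusted p = 0.176 with an estimated correlation), with LHCB4.2 at 0.43, the 1 gene that passed adjusted over the list alone. The 4 photosystem core genes PSAE-1, PSAN, PSBW and PSBY all lay above 0, with a median of 0.31 (adjusted p = 2.4e-04; adjusted p = 0.103 with an estimated correlation), and 2 of them, PSAE-1 at 0.32 and PSBW at 0.32, passed adjusted over the list alone. The light harvesting call was lost without replicate 1 of the 24 h control (adjusted p = 0.369), an array that stood apart on the second axis, and without replicate 1 of dexamethasone at 24 h (adjusted p = 0.325). Chlorophyll synthesis (9 genes, median 0.01, adjusted p = 0.509), electron transport (3 genes, 0.05, adjusted p = 0.363) and carbon fixation (3 genes, 0.05, adjusted p = 0.509) did not pass.

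**Figure D2:**
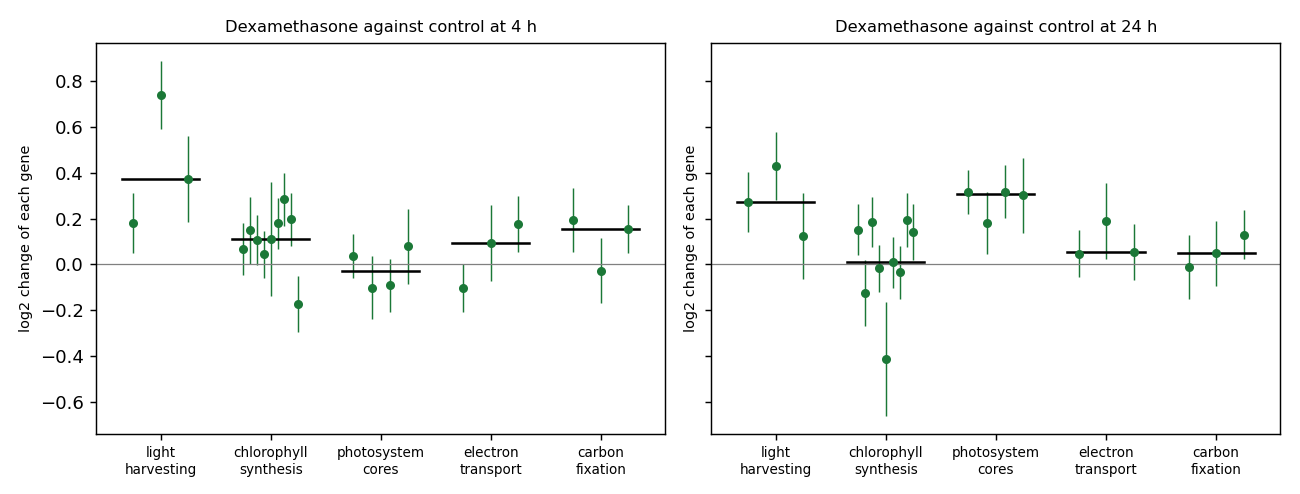
Log2 change of each tested gene of the 5 photosynthesis lists with dexamethasone at 4 h (left) and 24 h (right). Points are genes, vertical lines 1 standard error and black bars list medians; the 3 light harvesting genes lie above 0 at both times and the 4 photosystem core genes lie above 0 at 24 h.

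Of the lists written after the annotation had been seen, those of plastid-encoded genes passed as higher at 24 h. Of 42 photosynthesis genes encoded in the plastid, 41 lay above 0, with a median log2 change of 0.26 (adjusted p = 5.0e-13; adjusted p = 0.553 with an estimated correlation) and with psbT at 0.63. The list of plastid-encoded genes of transcription and translation passed with a median of 0.13 over 19 genes (adjusted p = 0.0059; adjusted p = 0.553 with an estimated correlation), lost without replicate 2 of the 24 h control (adjusted p = 0.576) or without replicate 2 of dexamethasone at 24 h (adjusted p = 0.357). The cell wall loosening list, mainly expansins, passed as higher with a median of 0.23 and 18 of 19 genes above 0, although no member passed (adjusted p = 2.8e-04; adjusted p = 0.553 with an estimated correlation), lost without replicate 1 of the 24 h control (adjusted p = 0.141), an array that stood apart on the second axis. In the controls from 0 h to 24 h the cell wall loosening list was lower, with a median of -0.14 and 15 of 19 genes below 0. Both comparisons use the 24 h control arrays, with opposite sign. The rise with dexamethasone therefore cannot be told apart from low values on these control arrays. The auxin list of 3 genes passed as lower, with a median of -0.29 (adjusted p = 0.0171; adjusted p = 0.553 with an estimated correlation). It was lost without either control array at 24 h (adjusted p = 0.140 and 0.0663) and without replicate 2 of dexamethasone at 24 h (adjusted p = 0.106), and with no filter (adjusted p = 0.376).

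The combined list of the 22 nuclear genes of the 5 photosynthesis lists passed as higher at 4 h (median 0.11, 17 genes above 0 and 5 below, adjusted p = 0.0123), at 24 h (0.14, 17 and 5, adjusted p = 0.0017) and on average (0.11, 19 and 3, adjusted p = 2.6e-05), with 0 members passing over all genes; with an estimated correlation the adjusted p was 0.553 in all 3. The call at 4 h was lost without replicate 1 of the 4 h control (adjusted p = 0.380) or without replicate 1 of dexamethasone at 4 h (adjusted p = 0.176). The call at 24 h was lost without replicate 1 of the 24 h control (adjusted p = 0.140) or without replicate 1 of dexamethasone at 24 h (adjusted p = 0.101). The autophagy list passed as higher at 4 h, with 9 of 10 genes above 0 and no member passing (median 0.13, adjusted p = 0.0340; adjusted p = 0.621 with an estimated correlation), with ATG8E, a ubiquitin-like protein of autophagosomes, at 0.81. That call was lost without replicate 2 of dexamethasone at 4 h (adjusted p = 0.871), an array that stood apart on the second axis, without replicate 1 of the 4 h control (adjusted p = 0.665), without replicate 1 of the 24 h control (adjusted p = 0.0674), or without replicate 1 of dexamethasone at 24 h (adjusted p = 0.0503), and with quantile normalization (adjusted p = 0.0575). Over the 16 lists, 9 passed in none of the 3 comparisons, with a smallest adjusted p of 0.0748: photosynthesis assembly, UDP-glycosyltransferases, glutathione transferases, cold and dehydration, iron homeostasis, rapid stress response, secretory stress, stomatal lineage and the root markers of the second set.

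The average over both times compared 4 dexamethasone arrays with 4 controls. The probe sets 249035_at (log2 change 4.67, SE 0.18, limma adjusted p = 1.2e-06) and 266273_at (2.62, SE 0.28, adjusted p = 0.0140) rose, and 0 fell; 620 had an unadjusted p below 0.05, or between 465 and 927 when 1 array at a time was left out. With all arrays, the 620 were fewer than the 729 expected by chance. The mean signal of 266273_at was 26.5 ± 12.2 with dexamethasone at 4 h and 28.4 ± 8.48 at 24 h (SD, n = 2), and no control array exceeded 2.67, while its signal of 17.8 on replicate 1 of dexamethasone at 4 h lay below percentile 40 of that array. All its control signals lay below percentile 40 too, so the size of its rise is uncertain. It did not pass at 4 h alone (2.59, adjusted p = 0.303) or at 24 h alone (2.66, adjusted p = 0.521). Its call on average was lost without any 1 of 7 of the 8 arrays, with log2 changes between 2.46 and 2.80. The call was also lost with the replicate number as a block (limma adjusted p = 0.0637). Light harvesting was higher with dexamethasone on average (median 0.25, adjusted p = 2.4e-04; adjusted p = 0.103 with an estimated correlation), with 2 of 3 genes passing adjusted over the list alone. Photosystem cores rose (0.15, adjusted p = 0.0397; adjusted p = 0.361 with an estimated correlation), and this call was lost without any 1 of 5 arrays, with adjusted p between 0.0908 and 0.369, and with quantile normalization (0.0508). The list of plastid-encoded photosynthesis genes passed as higher (0.10, adjusted p = 2.6e-05; adjusted p = 0.621 with an estimated correlation), lost without replicate 2 of the 24 h control (adjusted p = 0.255). The 2 times went opposite ways for this list, with a median of -0.09 at 4 h, where 25 of 42 genes lay below 0, and 0.26 at 24 h. The sugar transport list passed as higher, with 4 of 5 genes above 0 and no member passing (0.13, adjusted p = 0.0123; adjusted p = 0.553 with an estimated correlation), lost without replicate 1 of the 24 h control (adjusted p = 0.193), replicate 2 of dexamethasone at 4 h (0.0858) or replicate 1 of dexamethasone at 24 h (0.105), and with no filter (0.668). Chlorophyll synthesis (adjusted p = 0.0571), electron transport (0.325) and carbon fixation (0.184) did not pass on average.

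The other fixed lists were not tested, because 11 had 1 or 2 tested members and 5 had 0. The 5 were plastid import, salicylate defence, low oxygen, carbon starvation and cell division. HYH, a light signalling factor, had a log2 change of 0.46 at 4 h, and GI, a clock component, had -0.40; each passed adjusted over the list alone, a list of 1 tested gene, and not over all genes (adjusted p = 0.707 for both). At 24 h they had 0.01 and 0.02. LYC of carotenoid synthesis had 0.09 at 4 h and 0.04 at 24 h, NOL of chlorophyll breakdown 0.03 and 0.00, and the plastid gene expression list of 2 genes medians of -0.06 and -0.02. PDF1.2 of the jasmonate list had -0.12 and 0.29, GSTU25 of detoxification -0.36 and 0.30, and DFR of flavonoid synthesis 0.10 and 0.69. The root marker EXPA7 had 0.11 and 0.11, the stomatal marker FMA of the vascular and epidermal list 0.05 and -0.30, and the reference gene AT4G34270 0.05 and 0.07. None of these passed over all genes.

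Whether the effect of dexamethasone differed between 24 h and 4 h was tested directly. No probe set passed: limma gave 0, the smallest adjusted p was 0.832, and 799 had an unadjusted p below 0.05, or between 361 and 1868 when 1 array at a time was left out. Without replicate 1 of dexamethasone at 4 h there were 14. By chance 729 are expected, against the 799 with all arrays. Light harvesting gave no call (median -0.25, adjusted p = 0.450), and photosystem cores were higher at 24 h than at 4 h (median difference 0.28, adjusted p = 0.0202; adjusted p = 0.165 with an estimated correlation).

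In the controls, many transcripts changed between 0 h and 4 h without dexamethasone. The samples at 4 h come from another time of day than those at 0 h, under cycles of 16 h light and 8 h dark. Time of day and time since the start of treatment cannot be told apart in this comparison. COR27 (AT5G42900), a cold-regulated gene that acts in the circadian clock, rose from a signal of 4.70 ± 0.265 to 110 ± 2.61 (SD, n = 2), a log2 change of 3.67 (limma adjusted p = 5.5e-06). Its signal at 0 h lay below percentile 40 of the arrays, so the size of the rise is uncertain, as it is for AT1G07050, AT2G23910 and AT4G33980, whose 0 h signals also lay there. AT1G07050 rose by 3.166, AT2G23910 by 2.43, AT4G33980 by 2.07 and AT2G21130 by 2.05 on the log2 scale. AT5G62280 fell by 1.86 and the log2 changes were -1.74 for AT1G62510, -1.74 for AT3G15310, -1.68 for AT1G73480 and -1.62 for AT1G23390. The calls of AT1G62510, AT3G15310 and AT1G23390 were lost without any 1 of the 4 arrays compared, with log2 changes between -1.89 and -1.34. In limma without the trend AT1G62510 (adjusted p = 0.0550) and AT1G23390 (adjusted p = 0.0684) did not pass. AT1G23390 also lost its call with no filter (limma adjusted p = 0.0653). AT3G15310 lost its call with quantile normalization (limma adjusted p = 0.0597) and without either array of dexamethasone at 24 h. For AT3G15310 the signals at both times lay below percentile 40. Of the unnamed probe sets, 249850_at rose by 4.29 and 257985_at by 3.73, while 248910_at fell by 3.48 and 250665_at fell by 3.18. In each of these 4 the weaker of both mean signals lay below percentile 40, so these sizes are uncertain too.

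In all, 383 probe sets passed between 0 h and 4 h in the controls, 161 higher and 222 lower; 170 had a single gene, 73 higher and 97 lower. LHCB4.2 fell by 0.84 on the log2 scale (adjusted p = 0.0115) and PORB rose by 1.07 (adjusted p = 7.7e-04). The electron transport list rose (median 0.43, adjusted p = 0.0034; adjusted p = 0.329 with an estimated correlation), with NdhN, a subunit of the plastid NDH complex, at 0.85. The list of plastid-encoded photosynthesis genes passed as higher (40 of 42 above 0, median 0.52, adjusted p = 3.4e-19; adjusted p = 0.499 with an estimated correlation), as did plastid-encoded genes of transcription and translation (median 0.42, adjusted p = 1.5e-10; adjusted p = 0.458 with an estimated correlation). The median log2 level of the plastid-encoded photosynthesis genes was 9.41 and 9.83 on the control arrays at 0 h and 10.26 and 10.24 at 4 h, and the signal of 25S ribosomal RNA was 1642 and 2863 at 0 h and 2917 and 2964 at 4 h, so uneven carry-over of RNA without poly(A) tails was not separated from this change. The cold and dehydration list passed as higher (adjusted p = 0.0103; adjusted p = 0.499 with an estimated correlation) although its median was -0.01, since its mean of 0.93 rests on members such as COR27. The count fell to 134 without replicate 1 and 136 without replicate 2 of the 4 h control, and to 164 and 177 without replicates 1 and 2 of the 0 h control.

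COR27 was below percentile 40 of the arrays at 24 h as at 0 h, with 8.18 ± 0.578 in the controls, and it had with dexamethasone 128 ± 10.9 at 4 h and 9.65 ± 2.93 at 24 h (SD, n = 2). Between 0 h and 24 h in the controls limma called 0 probe sets, with 662 at an unadjusted p below 0.05 (between 539 and 1151 when 1 array at a time was left out) and a smallest adjusted p of 0.337. Without replicate 2 of the 24 h control 4 passed, and without replicate 2 of the 0 h control 1 passed. With all arrays, the 662 were fewer than the 729 expected by chance. The list of plastid-encoded photosynthesis genes passed as higher over this interval too (median 0.28, adjusted p = 1.1e-13; adjusted p = 0.562 with an estimated correlation), as did the combined nuclear photosynthesis list (median 0.13) and plastid-encoded genes of transcription and translation (0.11), both with adjusted p = 0.0133 (adjusted p = 0.666 with an estimated correlation), and the cell wall loosening list passed as lower (median -0.14, adjusted p = 0.0103; adjusted p = 0.666 with an estimated correlation). The plastid medians of 9.41 and 9.83 at 0 h differ by 0.42, more than the change of 0.28, and the signal of 25S ribosomal RNA was 700 and 913 at 24 h against 1642 and 2863 at 0 h, so the cause of this change is open. The median change of the nuclear list from 0 h to 24 h in the controls was thus about as large as that between dexamethasone and control at 24 h (median 0.14). Both changes use the 24 h control arrays, with opposite sign, so they are not independent. The change with dexamethasone is measured from the 24 h controls and comes on top of the other.

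The genes with the highest weight on the second axis of variation were examined on the 2 arrays that it sets apart, replicate 1 of the 24 h control and replicate 2 of dexamethasone at 4 h. They were chosen because they differ there, and no list or enrichment was tested on them. AT4G12500, a lipid transfer protein-like gene, had signals of 2011 and 2581 on them and between 44.9 and 96.7 on the other 8 arrays. AT5G64120, a peroxidase, had 3088 and 4384 against 317 to 455, and AT2G43620, a chitinase family gene, 1308 and 1287 against 131 to 332. AT2G38870 had 1780 and 1551 against 328 to 477. Leaving out both arrays, a choice made after the data were seen, gave 3 probe sets at 4 h, 1 at 24 h and 15 on average, 13 higher and 2 lower.

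**Figure D3:**
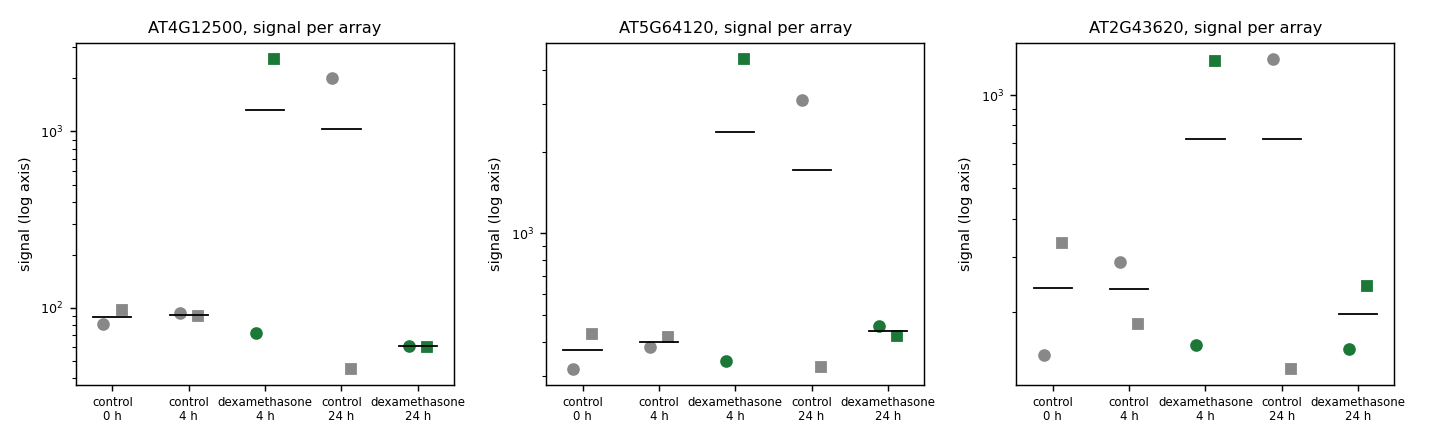
Signal of AT4G12500, AT5G64120 and AT2G43620 on each of the 10 arrays, on log axes, by group. Circles are replicate 1, squares replicate 2 and bars the group means; replicate 1 of the 24 h control and replicate 2 of dexamethasone at 4 h lie above the other 8 arrays, for AT4G12500 at 2011 and 2581.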

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

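The tests of RNA degradation, of exchanged labels and of the control array were chosen only after the results they bear on had been seen. All tests of lists in the difference between times were also added later. Each list named here differed between 24 h and 4 h by camera at the preset correlation, and none did with an estimated correlation.

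The dexamethasone effect on plastid-encoded photosynthesis genes was higher at 24 h than at 4 h by a median of 0.34 on the log2 scale (adjusted p = 1.3e-07; adjusted p = 0.429 with an estimated correlation). The control array that stood apart on the second axis did not account for the rise at 24 h, because the list median was 0.37 without that array, against 0.26 with it; it was 0.16 without the other control. Uneven carry-over of RNA without poly(A) tails stays open, as does an effect of dexamethasone, since the values disagree. The 9 tested transcripts encoded in mitochondria, which also lack stable tails, had a median of 0.14 at 24 h, which reached the bound of 0.13 set before the result was seen, but their log2 medians per array were 5.49 and 4.97 in the controls at 24 h and 5.01 and 5.26 with dexamethasone, which do not show a rise. The signal of 25S ribosomal RNA, looked at afterwards, was 700 and 913 in the controls at 24 h and 532 and 2319 with dexamethasone, while the plastid medians with dexamethasone were 10.23 and 10.23.

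The levels of the 50 genes with the highest weight on the second axis, which stand out on 2 arrays by the way they were chosen, were weighed against 3 technical explanations. Array brightness or scaling does not account for them, since all arrays had been scaled to a common mean before deposit. The median signal was 35.9 on the control array and 33.9 on the dexamethasone array, against 34.4 to 35.9 on the other 8. Quantile normalization left at least 99.91% of the median excess of the 50 genes, but on arrays scaled alike it could hardly have removed it. RNA degradation is argued against by a mean log2 ratio of 3' to 5' control probe sets of 0.36 and 0.35 on the 2 arrays, inside the range of 0.23 to 0.47 of the other 8. For exchanged labels, 249035_at had a signal of 15.3 on the control array and at least 290 on all dexamethasone arrays. It was chosen because it passed under these labels, so it cannot test them. Positions on the largest axis of variation, which uses no labels, argue against an exchange. The control array lay at -13.8, and the other arrays at 24 h between -17.3 and -13.5. The dexamethasone array lay at 21.6, and the other arrays at 4 h between 19.6 and 21.9. The arrays belong to different groups, so no biological explanation was tested.

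The photosystem core list differed by 0.28 (adjusted p = 0.0202; adjusted p = 0.165 with an estimated correlation). Plastid-encoded genes of transcription and translation differed by 0.25 (adjusted p = 0.0051; adjusted p = 0.429 with an estimated correlation). Cell wall loosening genes differed by 0.35 (adjusted p = 6.4e-04; adjusted p = 0.429 with an estimated correlation). The rapid stress response list differed by -0.63 (adjusted p = 0.0099) and the autophagy list by -0.15 (adjusted p = 0.0366), both with adjusted p = 0.429 with an estimated correlation. Of the arrays that stood apart on the second axis, 1 was a dexamethasone array at 4 h and 1 a control array at 24 h. With all arrays camera gave the rapid stress response list as higher at 4 h and lower at 24 h, without a call. Without both of these arrays both directions turned, to lower at 4 h and higher at 24 h. The difference of this list between times is therefore not shown apart from these arrays. No list difference between times was recomputed without them.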

How the results depend on the processing

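The omission of both arrays that stood apart on the second axis was chosen after the data were seen. For named genes, and lists called with dexamethasone at 4 h, at 24 h or on average, 3192 values were recomputed and 0 reversed. Of these, 3066 kept their direction and side of the threshold and 77 lost a call. Another 5, all of genes, gained a call without replicate 1 of dexamethasone at 4 h, and 44 that had not passed changed sign. Values that had not passed and again did not pass, in the same direction, count among the 3066. All 5 calls of lists fixed beforehand and all 10 of added lists were lost with an estimated correlation. At 24 h this correlation was -0.04 for photosystem cores and 0.0093 for auxin, below the preset 0.01. A higher correlation between genes therefore did not cause these losses. For the other calls the estimate was above 0.01. List calls in the difference between times and in the control time courses are not among the 3192. Lists without a call were followed only in number: shifts of lists fixed beforehand rose from 5 to 7 with no filter and without replicate 2 of the 4 h control.

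The count of genes changed by dexamethasone on average fell to 1 with the filter at percentile 60 and to 1 with the replicate block. Pairing of the samples by replicate number was not seen, though it is not excluded: of 10 correlations of deviations between groups 4 were below 0 and 2 above 0.1. The largest in size, -0.42, was between the 24 h control and dexamethasone at 4 h. Each of these groups holds an array that stood apart on the second axis, under different replicate numbers, so this value says little about pairing. In the controls between 0 h and 4 h the count was 228 in limma without the trend, where 219 were among the 383, and 145 with at least a 2-fold change. The number of list shifts was 0 of 5 with an estimated correlation. Leaving out both arrays gave 3 at 4 h, 15 on average and 639 between 0 h and 4 h in the controls. The cause of these differences was not tested.

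Leaving out each array in turn, the count ranged from 1 to 80 at 4 h, from 1 to 8 at 24 h, from 1 to 3 on average, from 0 to 14 for the difference between times, from 134 to 482 in the controls at 4 h and from 0 to 4 in the controls at 24 h. List shifts ranged from 3 to 7, and named values with their direction kept from 128 to 136. The 80 and the 14 came without replicate 1 of dexamethasone at 4 h, the 8 and the 4 without replicate 2 of the 24 h control, the 3 on average without replicate 2 of dexamethasone at 24 h, and 3 list shifts without replicate 1 of the 24 h control or of dexamethasone at 24 h. A group left with 1 array is assumed to vary like the others. Weak signals are limited by background, which the table does not give.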

Other observations

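The correlation between times and the count of splits were planned before their results were seen, but the rule for reading the correlation was changed afterwards. The values without both arrays that stood apart on the second axis were also chosen afterwards.

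Without both of these arrays, named genes passed on average that had not passed before. UGT88A1 rose by 0.63 on the log2 scale (SE 0.10, limma adjusted p = 0.0337), AT3G05640 by 1.55 (adjusted p = 0.0076), AT5G35970 by 0.91 (adjusted p = 0.0458), AT5G40450 by 0.86 (adjusted p = 0.0025) and NET1B, an actin-binding protein, by 0.76 (adjusted p = 0.0498). AT5G03350 rose by 1.27 (adjusted p = 9.2e-04), but it is among the 50 genes of the axis by which the left-out arrays were picked. AT1G07840 fell by 1.04 (adjusted p = 0.0256) and AT5G39520 by 0.95 (adjusted p = 0.0337). The chlorophyll synthesis list then passed at 4 h (adjusted p = 0.0356; adjusted p = 0.278 with an estimated correlation), and photosystem cores kept their call at 24 h (adjusted p = 0.0142; adjusted p = 0.278 with an estimated correlation). Light harvesting passed at 4 h (adjusted p = 0.0027) and on average (0.0142), and not at 24 h (0.362), all with adjusted p of 0.278 or more with an estimated correlation. Calls were lost for photosystem cores on average (adjusted p = 0.114), the combined nuclear photosynthesis list at 24 h (0.199), cell wall loosening at 24 h (0.179), auxin at 24 h (0.195), autophagy at 4 h (0.955) and sugar transport on average (0.848). Plastid-encoded genes of transcription and translation passed as lower at 4 h (adjusted p = 0.0120; adjusted p = 0.706 with an estimated correlation). Plastid-encoded photosynthesis genes then passed as lower at 4 h (adjusted p = 0.0307; adjusted p = 0.993 with an estimated correlation) and as higher at 24 h (adjusted p = 8.7e-17; adjusted p = 0.706 with an estimated correlation).

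A hypothesis that many probe sets respond alike to dexamethasone at both times was tested by the correlation of the log2 changes across 14574 probe sets, without 249035_at. Pearson's r was -0.18 and Spearman's rho -0.12 across genes, which are not independent replicates, and 10 of 18 relabellings of the arrays within times gave an r as high. Without both arrays that stood apart on the second axis r was 0.11. By the rule written beforehand, an r that was not positive counted against a shared response. A further condition, that r also be the lowest of the relabellings, was added after the value was seen. The value lies within the spread of the relabellings, so under the changed rule a shared response is neither shown nor excluded.

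Regrouping the arrays does not settle whether the count on average could arise by chance. Of the 35 splits of the 8 arrays into 4 and 4, 2 gave at least 2 probe sets, the real one included. The other was the split by time, with 1106, which reflects a structure of the samples and was fitted without the time term. With that split counted the share of splits could not have fallen under 0.05; the highest of the remaining splits was 1.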
